A study of Xenopus tropicalis with 11 samples.

How the data were processed

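Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on whole embryos of the Nigerian strain of the frog Xenopus tropicalis. Per the labels' protocols, embryos were grown at 25 °C and fixed in 1% formaldehyde for 45 min. Chromatin was sonicated to 200 to 500 bp, and 10 to 30 ng of DNA went into each library. The 11 samples are Foxh1 at stages 8 and 9, Tle at stage 8, Foxa at stage 10.25, RNA polymerase II in 4 samples and input DNA in 3 samples. A peak list was used for each of the 4 Foxh1, Tle and Foxa samples. The other 7 samples were not analysed here. The 2 further lists, Foxh1 and Smad2/3 of the early gastrula, belong to the whole series. Their stage is given by the names of the deposited lists and is slightly later than that of the Foxa sample. Per the labels they are a reanalysis of samples from an earlier series of which 5 were taken up.

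Per the submitters' processing notes, Bowtie 1.0.0, MACS2 2.0.10, SAMtools and HOMER 4.7 were used, with no role given for each. The genome build, the controls used in peak calling and the thresholds are not given in the sources used here. Per the labels, each Foxh1 list of stages 8 and 9 stands for 2 pooled replicates, and Tle and Foxa for 1 library each. The Tle library was made with a different kit and has an input sample of its own, per the labels.

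The deposited lists of Foxh1 and Smad2/3 have 10 columns in the layout of MACS2 narrow peaks. The authors' fold enrichment of each peak over the local background is 1 of them, and the deposited −log10 p of the peak is another. The deposited score of these lists is 10 times that −log10 p, rounded down, in 100% of peaks. The position of the summit is also given in these deposited lists, and it served as the peak centre. For Tle and Foxa peaks the middle of the peak was used as the centre instead. Distances between centres of these peaks and those of Foxh1 or Smad2/3 thus set a middle against a summit. The Tle and Foxa lists carry only a score from the authors' peak caller, with a minimum just above 3, and whether it stands for a p or a q is not given in the sources used here. Scores and folds are the authors' values, and they were used to describe, rank or split peaks within 1 list. The exceptions are the lowest folds and −log10 p of the Foxh1 lists, given side by side to show where each list ends, and 1 rank correlation of Foxh1 and Tle scores across peaks.

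Peaks of 2 lists were counted as shared when they overlapped by at least 1 base. Each share has a Wilson 95% interval, which covers the counting error of peaks and no variation between embryos. Chance was set by moving the second list by a random circular shift within each scaffold, 1000 times. The extent of a scaffold was taken as the furthest peak end in any list, over 1234 scaffolds and 1369.8 Mb in all. The one-sided permutation p cannot go below 0.000999 with this number of shifts, and it was adjusted over 15 pairs (12 planned before the data were examined and 3 added later) by the Benjamini-Hochberg method. These p-values describe the lists and not replicates, since neither replicate-level lists nor read numbers were used here, and the depth of the libraries is therefore unknown.

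The share of Foxh1 peaks with a Tle, Foxa or Smad2/3 peak was compared between peaks that were and were not shared with another Foxh1 stage, with the two-sided Fisher's exact test over counts of peaks. The 12 tests were adjusted together, and values below 1e-300 are given as 1e-300. The tests were repeated within 3 classes of equal size by the score of the Foxh1 list. Peaks are not replicates and neighbouring peaks are not independent, so intervals of some differences come from 1000 bootstrap draws of 5 Mb blocks. Regions were formed by merging overlapping peaks of all 6 lists. The area under the curve is the probability that a shared peak has a higher score than an unshared peak of the same list.

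The overlap test was tested on simulated data. Over 50 randomly moved copies of the stage 9 list, the median fold over chance against the stage 8 list was 0.997. Of these copies, 5 gave a p under 0.05, somewhat more than the nominal rate. The copies were moved by the same circular shift that sets chance. This checks the computation and not whether such shifts suit real lists. Planted shares of 5, 20 and 60% came back as 4.99, 19.8 and 59.6% above chance. An odds ratio of 8.14 was planted by marking stage 8 peaks at random, without a second list, and came back as 8.25. That checks the calculation of the odds ratio and not the overlap. Calculations were done in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

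Alternatives were another definition of a shared peak (centres within 100 bases, or an overlap of at least 50% of both peaks), stricter or equal-length lists, local shifts of 5 to 50 kb, uniform random placement, and the 10 longest scaffolds alone. Coordinates are those of the deposited lists, counted from 1. Gene names, distances to start sites, gene lists and motifs were planned only for the case that an annotation or sequence of the same build was at hand. The gene table at hand belongs to an assembly that could not be matched to the build of the lists, so these parts were not run and the 8 gene lists fixed beforehand have no result. By the rule fixed for that case, the text names the 3 peaks of highest score in each list by position.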

Results

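Binding of 4 proteins was mapped in Xenopus tropicalis embryos by ChIP-seq, from the blastula to the early gastrula. Foxh1 is a forkhead transcription factor that is supplied maternally and acts with Smad2/3, the transcriptional effectors of Nodal signalling. Tle is a co-repressor of the Groucho family, which binds DNA through other factors. Foxa is a forkhead factor of the endoderm and the organizer. Stages 8 and 9 are blastula stages around the onset of zygotic transcription, and stage 10.25 is the start of gastrulation. Foxh1 was profiled at stages 8 and 9 and in the early gastrula, Tle at stage 8, Foxa at stage 10.25 and Smad2/3 in the early gastrula. The gastrula lists of Foxh1 and Smad2/3 are of a stage slightly later than that of Foxa and are called gastrula Foxh1 and gastrula Smad2/3. There is 1 peak list per factor and stage, so no spread between replicates can be given, and the sequencing depth behind the lists is unknown.

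The Foxh1 lists of the blastula stages were of similar size. Foxh1 had 28611 peaks at stage 8 and 29935 at stage 9, with median widths of 307 and 292 bases, covering 10.1 and 10.2 Mb. Tle had 37919 peaks at stage 8 and Foxa 40925 at stage 10.25, covering 11.8 and 10.98 Mb. The gastrula lists were far shorter, with 1290 peaks for Foxh1 and 480 for Smad2/3. The gastrula Foxh1 list was ordered by fold enrichment and ended at a fold of 7.70, whereas the lists of stages 8 and 9 were ordered by score and reached down to folds of 3.88 and 4.79. The lowest deposited −log10 p went the other way, with 16.0 in the gastrula, 32.0 at stage 8 and 25.7 at stage 9. The gastrula list was thus the stricter one by its lowest fold and not by its lowest −log10 p, which also depends on the unknown depth. By the highest number in the peak names, the gastrula list held 4.61% of that number. The lists of stages 8 and 9 held 22.3 and 30.6%. The number of peaks is therefore not comparable between the gastrula and the blastula, and a stage 8 or 9 peak that is missing from the gastrula Foxh1 list is not shown to be unbound.

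The comparison of Foxh1 between stages asks how much of the binding present before and around zygotic activation was found again later. Of the stage 8 peaks, 17659 (61.7%, Wilson 95% interval 61.2 to 62.3%) overlapped a stage 9 peak, where 1.67% was found by chance. Of the gastrula Foxh1 peaks, 1213 of 1290 (94.0%, 92.6 to 95.2%) overlapped a stage 9 peak by at least 1 base. A stage 8 peak was present at 956 of them (74.1%, 71.6 to 76.4%). With an overlap of at least 50% of both peaks the shares were 51.0% (48.3 to 53.7%) for stage 9 and 53.3% (50.6 to 56.0%) for stage 8. These intervals overlap, so this setting did not set the stages apart. The shares were 88.9 and 69.9% with centres within 100 bases. Against the 1290 highest-scoring peaks of each blastula list they were 34.4 and 18.1%. The fold over chance was 36.9 for stage 8 peaks in the stage 9 list, 51.8 for gastrula peaks in the stage 8 list and 61.8 for gastrula peaks in the stage 9 list. Each had a one-sided permutation p of 0.000999, the smallest that 1000 shifts can give, and the same after adjustment. With shifts of 5 to 50 kb, which keep the local density of peaks, the 61.8-fold value was 27.7 and the other two were 25.9 and 32.6.

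Of the regions formed by merging overlapping peaks of all 6 lists, 40546 held a Foxh1 peak of at least 1 stage. Of these, 10790 (26.6%) had a peak at stage 8 only, 11939 (29.4%) at stage 9 only and 16537 (40.8%) at stages 8 and 9 but not in the gastrula. All 3 stages shared 945 regions (2.33%). A further 258 regions were shared by stage 9 and the gastrula alone, 3 by stage 8 and the gastrula alone, and 74 were found in the gastrula only.

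**Figure D1:**
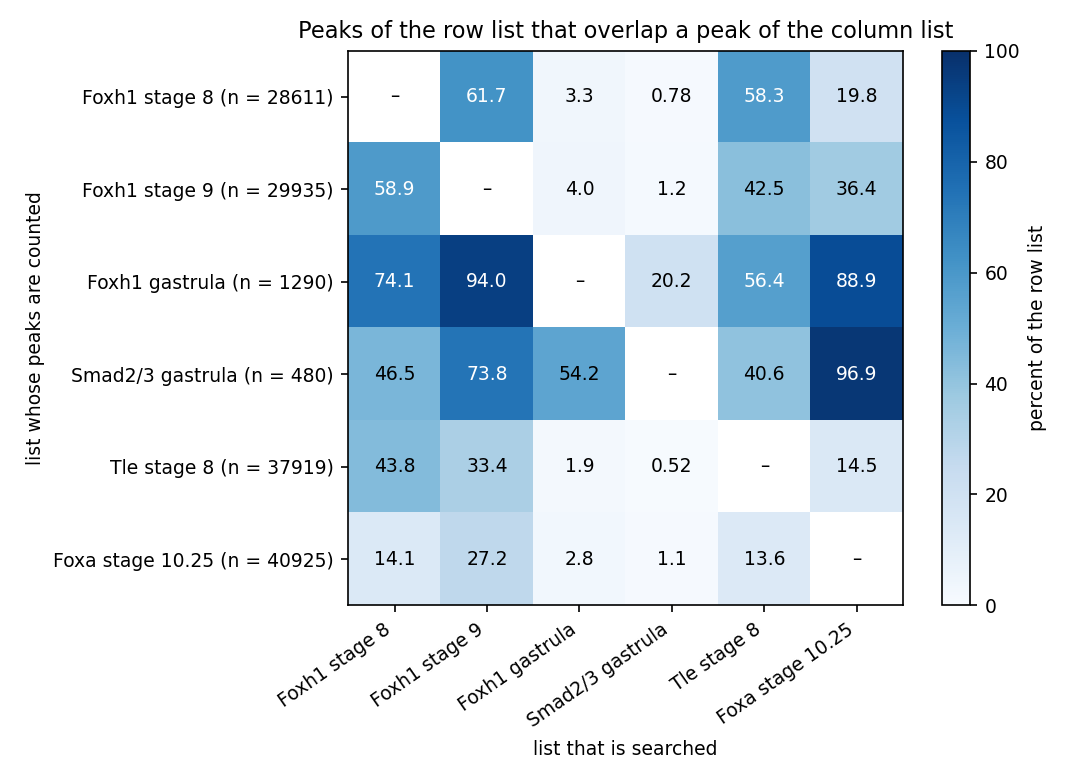
Percent of the peaks of each list (rows, with the number of peaks) that overlap a peak of each other list (columns) by at least 1 base; darker cells are higher percentages. Gastrula Foxh1 peaks overlap the stage 9 Foxh1 list in 94.0% and the Foxa list in 88.9%, while stage 8 Foxh1 peaks overlap Tle in 58.3% and Foxa in 19.8%.

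Tle and Foxh1 were compared to ask where the co-repressor and Foxh1 occupy the same regions. At stage 8, 16676 Foxh1 peaks (58.3%, 57.7 to 58.9%) overlapped a Tle peak, and 43.8% of the Tle peaks overlapped a stage 8 Foxh1 peak. The share was lower for Foxh1 peaks of stage 9, at 42.5% (41.9 to 43.0%), and stood at 56.4% (53.6 to 59.0%) for the short gastrula list. The overlap was 29.3 times chance for stage 8, 22.4 times for stage 9 and 34.0 times for the gastrula (one-sided permutation p = 0.000999 each). In the same order the folds were 77.3, 56.8 and 76.2 with centres within 100 bases. They were 83.1, 59.3 and 76.7 with an overlap of 50% of both peaks, and 21.2, 16.8 and 24.8 with shifts of 5 to 50 kb. The order of stage 8 and the gastrula thus depended on the setting. Tle peaks shared with stage 8 Foxh1 had higher scores than other Tle peaks, with medians of 12.7 against 5.78 and an area under the curve of 0.818. Among the 2862 stage 8 Foxh1 peaks of highest score 93.5% had a Tle peak, against 34.0% of the 2861 of lowest score. Among equal numbers of peaks of highest fold enrichment, 1290 per list, the Tle share was 94.0% at stage 8, 75.0% at stage 9 and 56.4% in the gastrula, a selection added after the data were examined. These 1290 peaks are the whole gastrula list but only the highest part of the blastula lists, so this fall may come from the selection. In the upper 50% of each list by score, Tle included, the shares were 62.8, 43.8 and 60.9%, with no steady fall. With the Tle list shortened to its 1290 highest-scoring peaks, 9.38% of the gastrula Foxh1 peaks had a Tle peak. The Tle and Foxh1 libraries of stage 8 came from different kits and inputs, and the Tle list rests on 1 library.

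Foxa and Foxh1 were compared to ask whether regions with Foxh1 early carry Foxa in the gastrula. The overlap with the Foxa list rose with the Foxh1 stage. Foxa peaks were found at 5657 stage 8 Foxh1 peaks (19.8%, 19.3 to 20.2%), at 10886 stage 9 peaks (36.4%, 35.8 to 36.9%) and at 1147 gastrula peaks (88.9%, 87.1 to 90.5%). These were 10.6, 19.4 and 44.4 times chance (one-sided permutation p = 0.000999 each). Foxa peaks shared with gastrula Foxh1 were among the higher ones of the Foxa list, with a median score of 47.8 against 10.6. Among the 1290 peaks of highest fold enrichment of each list, a selection added after the data were examined, the Foxa share was 35.7% (33.2 to 38.4%), 61.3% (58.6 to 63.9%) and 88.9%. Here too the 1290 peaks are the whole gastrula list. In the upper 50% of each list by score, Foxa included, the shares were 17.4, 35.5 and 92.4%. With centres within 100 bases, the Foxa shares of all peaks at stages 8 and 9 and in the gastrula were 14.9, 29.2 and 70.9%. They were 13.9, 29.0 and 67.4% with an overlap of 50% of both peaks. With shifts of 5 to 50 kb the folds were 7.60, 11.2 and 17.8. With the Foxa list shortened to its 1290 highest-scoring peaks, 24.8% of the gastrula Foxh1 peaks had a Foxa peak.

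Smad2/3 and Foxh1 were compared to ask how far the Nodal effectors of the gastrula lie at regions with earlier Foxh1. A stage 9 Foxh1 peak was present at 354 of the 480 Smad2/3 peaks (73.8%, 69.6 to 77.5%). A stage 8 Foxh1 peak was present at 223 (46.5%, 42.0 to 50.9%) and a gastrula Foxh1 peak at 260 (54.2%, 49.7 to 58.6%). The fold over chance was 36.3, 30.1 and 169 in that order (one-sided permutation p = 0.000999 each). The chance means were 9.76, 7.41 and 1.54 peaks, since the gastrula Foxh1 list is far shorter. The 169-fold value is therefore not comparable with the folds of the blastula lists. From the other side, 20.2% of the gastrula Foxh1 peaks had a Smad2/3 peak. With shifts of 5 to 50 kb the folds were 16.8, 17.9 and 71.8. The 169-fold value rests on a chance mean of 1.54 peaks and reached 326 with centres within 100 bases, 411 with an overlap of 50% of both peaks, 726 in the upper 50% of each list and 955 on the 10 longest scaffolds. Against the 480 highest-scoring Foxh1 peaks of each list the shares were 10.4% for stage 9, 6.04% for stage 8 and 39.6% for the gastrula, so that the gastrula share was then the highest. With an overlap of 50% of both peaks the stage 9 and gastrula shares were 51.5 and 52.1%.

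Stage 8 Foxh1 peaks were then split by whether Foxh1 was found there again at stage 9. Foxa peaks were found at 5353 of the 17659 shared peaks (30.3%) and at 304 of the 10952 others (2.78%), an odds ratio of 15.2 (95% interval 13.5 to 17.1; two-sided Fisher's exact p = 1e-300). Smad2/3 peaks were found at 222 of the shared peaks and at 2 of the others (odds ratio 69.7, 17.3 to 281; Fisher's exact p = 9.35e-44). That Smad2/3 value rests on the 2 peaks and fell to 12.7 (188 against 10 peaks) with centres within 100 bases and to 3.39 (144 against 31) with an overlap of 50% of both peaks, where the Foxa value was 12.2 and 9.76. Tle peaks were found at 61.4% of the shared and 53.3% of the other peaks, an odds ratio of 1.40 (1.33 to 1.47; Fisher's exact p = 7.76e-42). Within 3 classes of equal size by Foxh1 score the Tle relation turned round, with odds ratios of 0.763, 0.694 and 0.895 from the lowest to the highest class, the last with an interval of 0.770 to 1.04. The Foxa odds ratio was 14.3, 13.8 and 17.9 in the same classes. Over all stage 8 peaks, chance was 1.86% for Foxa, or 2.60% with shifts of 5 to 50 kb, and 0.0266% for Smad2/3. The Foxa share of 2.78% at peaks not shared with stage 9 thus lay near chance. Their Smad2/3 share was 0.0183%. Chance was not computed for these peaks alone.

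Stage 8 Foxh1 peaks were also split by whether gastrula Foxh1 was found there. Of the 954 stage 8 peaks with a gastrula Foxh1 peak, 92.1% had a Foxa peak and 20.6% a Smad2/3 peak, against 17.3% and 0.0976% of the 27657 others. The odds ratios were 56.1 (44.2 to 71.2; two-sided Fisher's exact p = 1e-300) and 266 (177 to 401; Fisher's exact p = 1.82e-266). Tle peaks were found at 72.5% against 57.8% (odds ratio 1.93, 1.67 to 2.23; Fisher's exact p = 1.70e-20). By score class the Tle odds ratio went opposite ways, with 0.780 (0.514 to 1.19) in the lowest and 0.674 (0.504 to 0.902) in the middle class. It was 1.46 (1.17 to 1.83) in the highest class, which held 667 of the 954 peaks. Pooled over the classes, the Tle odds ratio was 1.06 (block bootstrap interval 0.910 to 1.23). The unsplit value of 1.93 was not reached in any class. Because the pooled value joins classes of opposite direction, it describes none of them, and the Tle relation depended on the score class. The Foxa odds ratio was 20.1 with centres within 100 bases, 34.4 with an overlap of 50% of both peaks, 32.0 in the middle score class and 94.5 in the upper 50% of each list, where the Smad2/3 value was 487.

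Foxh1 peaks of a single blastula stage differed in the opposite sense for Tle and Foxa, in a comparison added after the data were examined. Tle peaks were found at 5830 of 10949 peaks of stage 8 only (53.2%) and at 1847 of 12031 of stage 9 only (15.4%), an odds ratio of 6.28 (5.90 to 6.68; two-sided Fisher's exact p = 1e-300). Foxa peaks were found at 302 (2.76%) and 5329 (44.3%) of the same peaks (odds ratio 0.0357, 0.0316 to 0.0402; Fisher's exact p = 1e-300). Smad2/3 peaks were found at 2 and 82 of them (Fisher's exact p = 8.76e-21). From the lowest to the highest score class the Tle odds ratio was 4.47, 8.29 and 16.2. The Foxa odds ratio was 0.0542, 0.0319 and 0.00842 in the same classes. Stage 9 peaks that already had Foxh1 at stage 8 had Tle in 61.4% and Foxa in 30.2%, against 15.3% and 45.2% of the other stage 9 peaks. The Foxa odds ratio of this split was 0.524, and 0.172, 0.225 and 0.278 from the lowest to the highest score class. The Smad2/3 shares were 1.26% and 1.07% (Fisher's exact p = 0.142), but within the score classes Smad2/3 was less frequent at peaks that already had Foxh1 at stage 8, with odds ratios of 0.181, 0.107 and 0.698 (Fisher's exact p = 0.00103, 1.57e-10 and 0.0196).

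**Figure D2:**
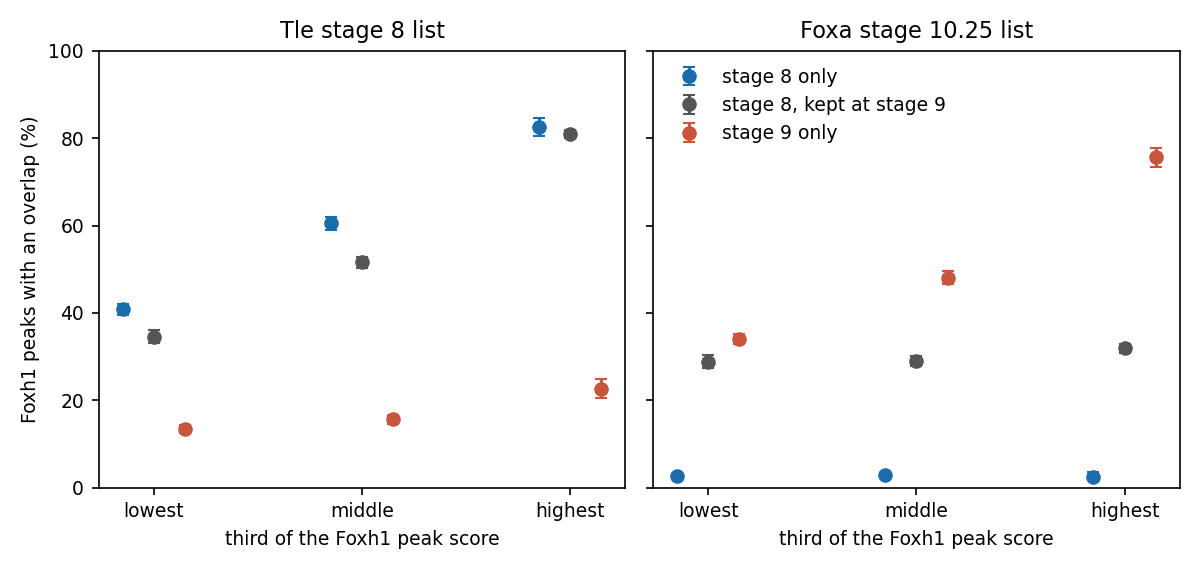
Percent of Foxh1 peaks that overlap the Tle list of stage 8 (left) and the Foxa list of stage 10.25 (right), by class of the Foxh1 peak score, for peaks of stage 8 only, stage 8 peaks shared with stage 9, and peaks of stage 9 only. Bars are Wilson 95% intervals over counts of peaks; Foxa stays between 2.55 and 2.87% at peaks of stage 8 only and rises from 34.1 to 75.7% at peaks of stage 9 only.

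Shared peaks tended to have higher scores than unshared peaks of the same list, with an area under the curve above 0.5 in all 30 ordered pairs of lists. For Smad2/3 peaks with a Foxa peak it was 0.728, with 15 unshared peaks, and with centres within 100 bases it was 0.534 (0.470 to 0.599), which does not exclude 0.5. Stage 8 Foxh1 peaks with a stage 9 peak had a median score of 680 against 447 (area under the curve 0.736). Stage 9 peaks with a gastrula peak had a median of 1402 against 498 (0.889). Foxa peaks with a Smad2/3 peak had a median of 65.5 against 10.7 (0.913). For the stage 8 Foxh1 list, 96.4% of the 2862 peaks of highest score were found at stage 9, against 36.3% of the 2861 of lowest score.

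The highest stage 8 Foxh1 peak lay on scaffold 7 from 1854579 to 1855041, with a score of 2239 and a fold enrichment of 52.3, and all 6 lists had a peak there. The other two of the 3 highest stage 8 peaks, on scaffold 2 from 106251251 to 106251675 and on scaffold 3 from 42208081 to 42208527, had peaks of stage 9 Foxh1 and Tle and none of Foxa, Smad2/3 or gastrula Foxh1. The highest stage 9 peaks lay on scaffold 3 from 3425516 to 3426103, on scaffold 5 from 118190466 to 118191171 and on scaffold 100 from 176362 to 177017, and each was also found at stage 8 and in the gastrula. The highest gastrula Foxh1 peaks lay on scaffold 3 from 5673226 to 5673610, on scaffold 7 from 1854610 to 1854988 and on scaffold 5 from 118186409 to 118186797, and all 3 had Smad2/3 and Foxa peaks.

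The highest Smad2/3 peak, on scaffold 1 from 202940577 to 202941194, was shared by all 6 lists. The next 2, on scaffold 7 from 123170862 to 123171453 and on scaffold 8 from 82252401 to 82252744, had Foxh1 at stage 9 and in the gastrula and Foxa but neither stage 8 Foxh1 nor Tle. The highest Tle peaks lay on scaffold 6 from 133029295 to 133030011, on scaffold 1 from 69463383 to 69464426 and on scaffold 7 from 98696036 to 98697321. All 3 had stage 8 Foxh1 and none had Foxa or Smad2/3. The highest Foxa peaks lay on scaffold 3 from 108796086 to 108796675, on scaffold 237 from 120020 to 120639 and on scaffold 8c from 1493714 to 1494251. All 3 had stage 9 Foxh1, 1 of them also stage 8 Foxh1, and none had Smad2/3.

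The 200 kb window with the most gastrula Foxh1 peaks, chosen after the data were examined, lay on scaffold 5 from 118057779 to 118257778. It held 12 gastrula Foxh1 peaks and 8 Smad2/3 peaks, with 13 Foxh1 peaks at stage 8, 18 at stage 9, 8 Tle peaks and 21 Foxa peaks. The window on scaffold 9 from 44221115 to 44421114 held 8 gastrula Foxh1 peaks and 36 Foxa peaks but 1 Smad2/3 peak.

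**Figure D3:**
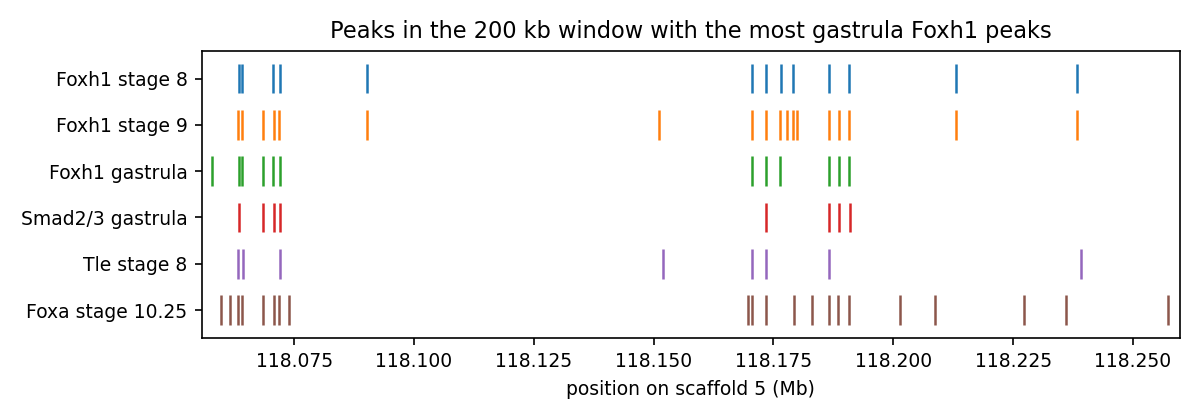
Peaks of the 6 lists (rows) along 200 kb of scaffold 5 (position in Mb); each line marks the centre of 1 peak of the window. The 12 gastrula Foxh1 peaks and the 8 Smad2/3 peaks fall mostly into clusters that also hold Foxh1 peaks of stages 8 and 9 and Foxa peaks.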

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

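The comparison of peaks of stage 8 only with peaks of stage 9 only, and the tests of weaker calls and of background in the Foxh1 library alone for the Foxa pattern, were chosen after the result was seen, as was the split of the Tle share by score class.

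The contrast between Foxh1 peaks of stage 8 only and of stage 9 only went opposite ways for Tle and Foxa. The log2 odds ratio for Tle exceeded that for Foxa by 7.46 (95% interval 7.25 to 7.66, over peaks, not replicates), and a test of the difference itself marked it out.

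Foxa peaks of stage 10.25 were found far more often at stage 8 Foxh1 peaks that were shared with stage 9 than at the others. Weaker calls among the others do not account for it, since the lowest odds ratio over classes of score was 13.8. Place along the scaffold and peak width are argued against in the same way, with lowest values of 13.5 and 12.1, and background of the Foxh1 library alone by the Tle share of 53.3% at the others. Background common to antibodies on stage 8 chromatin cannot be told apart from joint binding, because both predict that the Foxh1 and Tle scores rise together across those peaks, as they did (Spearman rho 0.294). The difference in stage between the factors and antibody cross-reactivity between forkhead factors stay open as untested.

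Tle peaks of stage 8 were found less often at Foxh1 peaks of stage 9 only than at those of stage 8 only. Weaker calls are argued against by the lowest odds ratio over score classes, 4.47. Whether the Tle list misses the regions of these stage 9 peaks stays open, although their Tle share was 3.50 percentage points higher with than without a Foxa peak (block bootstrap interval 2.15 to 4.88), the outcome set beforehand as counting against it. That outcome was badly chosen, because missing regions would lower the level of both shares (17.3 and 13.8%, against 53.2% at stage 8 only) and need not make them equal, and in the lowest score class they were 13.4% each. No biological explanation was tested, and since Tle was profiled at no other stage, stage and antibody stay open.

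In 4 of the 6 lists the numbers in the peak names run higher than the list is long, while in the Tle and Foxa lists they end at the number of peaks. They reach 128020 in the stage 8 Foxh1 list, 97775 at stage 9, 28001 in the gastrula Foxh1 list and 6247 in the Smad2/3 list, so that the listed peaks are 22.3, 30.6, 4.61 and 7.68% of the highest number. Peaks under the listed ones were not analysed here.

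Scaffold 480 held 11 gastrula Foxh1 peaks and 3 Smad2/3 peaks, and 0 peaks of the other lists. The furthest peak ended at base 41663, and the length of the scaffold is not known. Both lists with peaks there come from the earlier series, so stage and series cannot be told apart. The fold enrichment of the Foxh1 peaks ran from 7.78 to 21.9 with a median of 11.7. Over all 87 scaffolds with a gastrula Foxh1 peak, 3 had no peak of stage 8 or 9 Foxh1, Tle or Foxa.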

How the results depend on the processing

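The score classes, named in the design for stage 8 peaks, were listed as alternatives only after the data were examined, as were the splits of stage 9 peaks and the 3 pairs without a planned test. No paired analysis was possible because there is 1 list per factor and stage. All 105 alternatives of fold over chance stayed above 1 with a permutation p under 0.05, and the lowest was 6.67, with shifts of 5 to 50 kb. In the main setting all 15 pairs had the smallest p the shifts can give, so the test sets no pair of factors apart. The shifts do not keep features of sequence or chromatin that lists of any factors may share, and these were not tested. Of 72 alternatives of odds ratios, 62 kept their direction and side of the threshold, though not their size: for stage 8 peaks shared with stage 9 the Smad2/3 value ran from 3.39 (overlap of 50% of both peaks) to 159 (upper 50% of each list, with 0 Smad2/3 peaks among the others). Within score classes the Tle odds ratio reversed to 0.763, 0.694 and 0.895 for stage 8 peaks shared with stage 9, and to 0.780 and 0.674 in the lowest and middle class for those shared with the gastrula. Shared peaks score higher and peaks of higher score overlap Tle more often, so the unsplit value mixes both. The Smad2/3 odds ratio of stage 9 peaks with stage 8 Foxh1 (1.18, not past the threshold) reversed to 0.181, 0.107 and 0.698 by class and to 0.734 with an overlap of 50% of both peaks, and rose past the threshold to 1.43 in the upper 50% of each list; the cause was not tested. Of the 75 percentages that a setting can move, 59 moved by more than their interval, as did 13 of 30 areas under the curve, the lowest being 0.534 for Smad2/3 peaks with Foxa. That pair, with 15 unshared peaks, was taken in only after a minimum of 20 was lowered to 10. Gene, start site and motif alternatives, including shifts to other genes, were not run. Depth is unknown, list lengths follow thresholds, and a missing peak is not absence of binding.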

Other observations

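All comparisons of position, the 3 added overlaps and the test of stricter selection were chosen after the data were seen.

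Counted over all Smad2/3 peaks, with or without Foxh1, most lay at Foxa regions. Foxa peaks were present at 465 of the 480 Smad2/3 peaks (96.9%, Wilson 95% interval 94.9 to 98.1%; 36.5 times chance, or 14.8 with shifts of 5 to 50 kb). Tle peaks of stage 8 were present at 195 of them (40.6%, 36.3 to 45.1%; 21.4 times chance). The share was lower for Tle peaks, of which 5507 had a Foxa peak (14.5%, 14.2 to 14.9%; 8.44 times chance). With an overlap of at least 50% of both peaks that last share was 9.13%. The Foxa share of the Smad2/3 peaks was then 84.2%, and 80.8% with centres within 100 bases. Against the 480 highest-scoring Foxa and Tle peaks, the Smad2/3 shares were 19.0 and 1.46%. Each overlap had a one-sided permutation p of 0.000999, the smallest the shifts can give. The union of the lists held 88697 regions, of which 58172 had peaks of 1 list and 156 of all 6.

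Along the 10 longest scaffolds, peaks of the later lists lay nearer to the scaffold ends. The median distance to the nearer end, as a percent of the scaffold extent, was 28.8 for stage 8 Foxh1, 27.4 for stage 9, 25.7 for Foxa, 23.1 for gastrula Foxh1 and 21.2 for Smad2/3, while Tle stood at 28.8. Within 10% of an end lay 12.1% of the stage 8 and 23.1% of the gastrula Foxh1 peaks.

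Stricter selection of the gastrula Foxh1 list by fold is argued against as the whole cause. The 1290 stage 8 peaks of highest fold lay 4.29 percentage points further from the end than the gastrula peaks (block bootstrap interval 2.09 to 7.54). For the 1290 stage 9 peaks of highest fold it was 1.95 points (0.701 to 4.43). Such selection may account for part, because it moved the stage 9 median from 27.4 to 25.0. The other series as the source of the gastrula values stays open, because both gastrula lists come from it. The comparison within this series held no gastrula peak and cannot decide it. There, peaks of stage 8 only lay 3.51 points (1.95 to 5.54) further from the end than peaks of stage 9 only. For the whole lists, stage 8 minus stage 9, it was 1.47 points (0.784 to 2.48). The first of these differences was above 0 on 9 of the 10 scaffolds, the exception being scaffold 3 at -2.40. A step between stages 8 and 9 was thus present without the other series. Sequence composition and gene density near the ends may contribute and were not tested, so no biological explanation is put forward.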
